A study of Sus scrofa with 6 samples.

How the data were processed

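Gene expression was measured in sow ovary and in uterine tissue labelled myometrium at 3 stages, namely non-pregnant, early pregnant and late pregnant. Per the labels' protocols, tissue was washed in buffered saline and frozen in liquid nitrogen, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA for Affymetrix single-channel arrays. There were 6 arrays, 1 for each tissue and stage. The design text counts 9 pigs, 3 per stage. Whether an array carried RNA of a single animal or of several animals combined is not given in the sources used here. Each group therefore had 1 array and no replicates.

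The deposited values are intensity values on a linear scale, which the authors made with MAS5 per the submitters' processing notes. MAS5 condenses the probes of a probe set, including mismatch controls, into a signal. The MAS5 version and settings are not given in the sources used here. On every array the mean after trimming 2% of the probe sets at each end was 500.1, so the authors had scaled the arrays to a common level. Such scaling hides any change in the total amount of RNA, and a rise of many transcripts, beyond the 2% trimmed, can lower all others. The table held 24123 probe sets, of which 124 were control probe sets and were left out, leaving 23999. Every column was matched to its sample.

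Signals under a floor were raised to it before log2 was taken. The floor was 81.7, the 40th percentile of all signals on the 6 arrays. A ratio with the dimmer array at the floor is a lower bound and is written as "at least". Gene names came from a table of the platform's annotation: 10069 probe sets had 1 gene symbol, 198 had several and 13732 had none. Symbols were checked against current gene records by gene identifier for 9961 probe sets and kept from the platform table for 108, and 0 were changed. Probe sets with several symbols, with none, or with a locus number alone were counted but not named, which left 9774 probe sets of 6567 genes. The brightest probe set stood for a gene with several, and 2207 genes had several. No genome came with the data, so gene positions were not analysed here.

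The tissues were compared with limma 3.58.1 in R 4.3.3, by an additive fit of tissue and stage to the 6 arrays with an intensity trend in the variance prior. The fit has 2 residual degrees of freedom, and its residual holds any difference of the stage effect between tissues as well as noise. Probe sets above the floor on at least 2 arrays, 15882 in all, were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit gave the stage changes shared by the tissues. Arrays of a tissue are different stages and not replicates, and the tissues may come from the same pigs. The p-values thus measure agreement across these arrays and not across animals.

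Stages within a tissue were compared without a test, because each side is 1 array. The probe sets at 2-fold or more were counted among those above the floor on at least 1 of the arrays compared. As a technical check, the brightest and the next probe set of a gene were set side by side on the same arrays.

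Before the data were examined, 33 gene lists were fixed, covering steroid and cholesterol synthesis, ovarian and uterine cell types, contraction, matrix, vessels, immune cells, cell cycle, stress and housekeeping genes. Between tissues, lists were tested with camera in limma, with a preset correlation of 0.01 and, as an alternative, an estimated one, on 1 probe set per gene. Counts of list members past the threshold came from the fit to all tested probe sets. Between stages, a list's median log2 ratio was placed among 10000 random lists of the same size matched on decile of mean signal, and called when it lay outside the middle 95%. This describes these arrays and is not a test of the stages. Lists with fewer than 4 measured genes got no median. A list's measured genes were those above the floor on at least 1 of the arrays compared.

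Also fixed beforehand was the rule for named genes. Between tissues it took up to 12 genes per direction by log2 difference among those past the threshold, above the floor on all 6 arrays and in the same direction at all 3 stages, plus up to 6 per direction by bound among those at the floor on every array of the dimmer tissue. Within a tissue it took the 8 highest and 8 lowest genes measured on both arrays and up to 3 per direction by bound. From each list up to 4 members with the largest log2 values were taken. A list of placental markers and a list of luteal and granulosa cell markers were added after some of their members had been seen.

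The alternatives were a floor at the 25th percentile (33.7) or the 60th (246.2), a pseudocount of 16 with no floor, quantile normalization, centring on the median, no filter on low signals, no intensity trend, no stage block, leaving out arrays, and the mean of a gene's probe sets. The number of arrays limits the precision of every value. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

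The steps were tested on simulated data. For the comparison of ovary with myometrium, 200 changed probe sets among 15882 were simulated with the residual spread of these arrays. Of 50 probe sets per size, 0 were recovered at a log2 difference of 1, 14 at 2, 37 at 4 and 40 at 6, with 1 false call. The spread of each probe set was the one estimated on 2 residual degrees of freedom. The noise was independent between probe sets, and no stage effect was simulated. These counts thus describe the simulation and are no error rates for the real arrays. In simulated lists of 15 genes, 4.5% of 200 unchanged lists lay outside the middle 95%, against 61.5% of lists shifted upward by 0.5 on the log2 scale and 100% of those shifted by 1. The simulated genes varied independently of each other. The 4.5% is thus no error rate for real lists, whose members can vary together. Of 186 list medians between stages, 45 lay above and 47 below the middle 95%.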

Results

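Expression of 23999 probe sets was measured on 6 arrays, 1 for each of ovary and tissue labelled myometrium from non-pregnant, early pregnant and late pregnant sows. The myometrium is the smooth muscle wall of the uterus. Between 57.4% and 61.6% of the probe sets on an array lay above the floor of 81.7. Across the 11733 probe sets above it on all arrays, which are not independent replicates, the ovary arrays correlated with each other at Pearson's r of 0.953 to 0.967 on the log2 scale. Among arrays labelled myometrium, r was 0.876 between the non-pregnant and early pregnant arrays, 0.835 between the non-pregnant and late pregnant arrays and 0.928 between the pregnant arrays. The non-pregnant ovary and the non-pregnant array labelled myometrium correlated at 0.874. Hybridisation controls, which are added in equal amounts, read 0.46 above the mean of the arrays on the log2 scale on the non-pregnant ovary array and between -0.21 and 0.07 on the others. The ratio of the 3' to the 5' GAPDH probe set, a measure of RNA quality, was 2.33, 1.99 and 1.51 on the ovary arrays in order of stage and 1.52, 1.70 and 1.53 on the arrays labelled myometrium.

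Averaged over the stages, the ovary arrays carried genes of luteal and granulosa cells, whereas the arrays labelled myometrium carried genes of epithelium. RLN2, which encodes the hormone relaxin, had a mean signal of 24196 ± 11458 (SD, n = 3 arrays of different stages) in ovary and 115 ± 37.6 in tissue labelled myometrium. EPCAM, an adhesion molecule of epithelial cells, showed the opposite pattern, with 10256 ± 589 on the arrays labelled myometrium and 142 ± 44.5 on the ovary arrays. Smooth muscle genes were not higher on the arrays labelled myometrium. ACTA2, smooth muscle actin, had a mean signal of 21590 ± 2646 in ovary and 11772 ± 3642 on the arrays labelled myometrium, and its difference did not pass the test (adjusted p = 0.112).

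Of 19 measured genes of the uterine epithelium list, 13 were higher on the arrays labelled myometrium, 0 were higher in ovary and 6 did not pass. Adjusted over the list alone, 17 were higher there. The list's median log2 difference, ovary minus myometrium, was -3.73 (camera adjusted p = 1.06e-17, but adjusted p = 0.542 with an estimated correlation), and -2.71 with averaged probe sets. EPCAM differed by -6.21 ± 0.26 (SE, adjusted p = 0.00358), the keratin KRT19 by -5.75 and the cadherin CDH1 by -5.23. KRT18 lay under the floor on each ovary array and differed by -5.75 or below, and KRT19 lay under it on the late pregnant ovary array. By stage, the median was -2.94 in the non-pregnant, -4.18 in the early pregnant and -4.76 in the late pregnant pair of arrays. UABP-2, a protein secreted with uteroferrin, did not pass (adjusted p = 0.131), with a signal of 63.8 on the non-pregnant array and 26905 on the early pregnant array labelled myometrium.

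Of the 21 measured genes of the smooth muscle list, 0 passed, over all genes or adjusted over the list alone. Its median lay toward ovary at 0.68 (camera adjusted p = 0.00943, but adjusted p = 0.784 with an estimated correlation). DES, TPM2, MYLK and TAGLN had log2 differences of 1.22, 1.17, 1.06 and 1.01 toward ovary. The median was 0.56 at the non-pregnant and 0.77 at the early pregnant stage, and turned to -0.038 at the late pregnant stage.

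**Figure D1:**
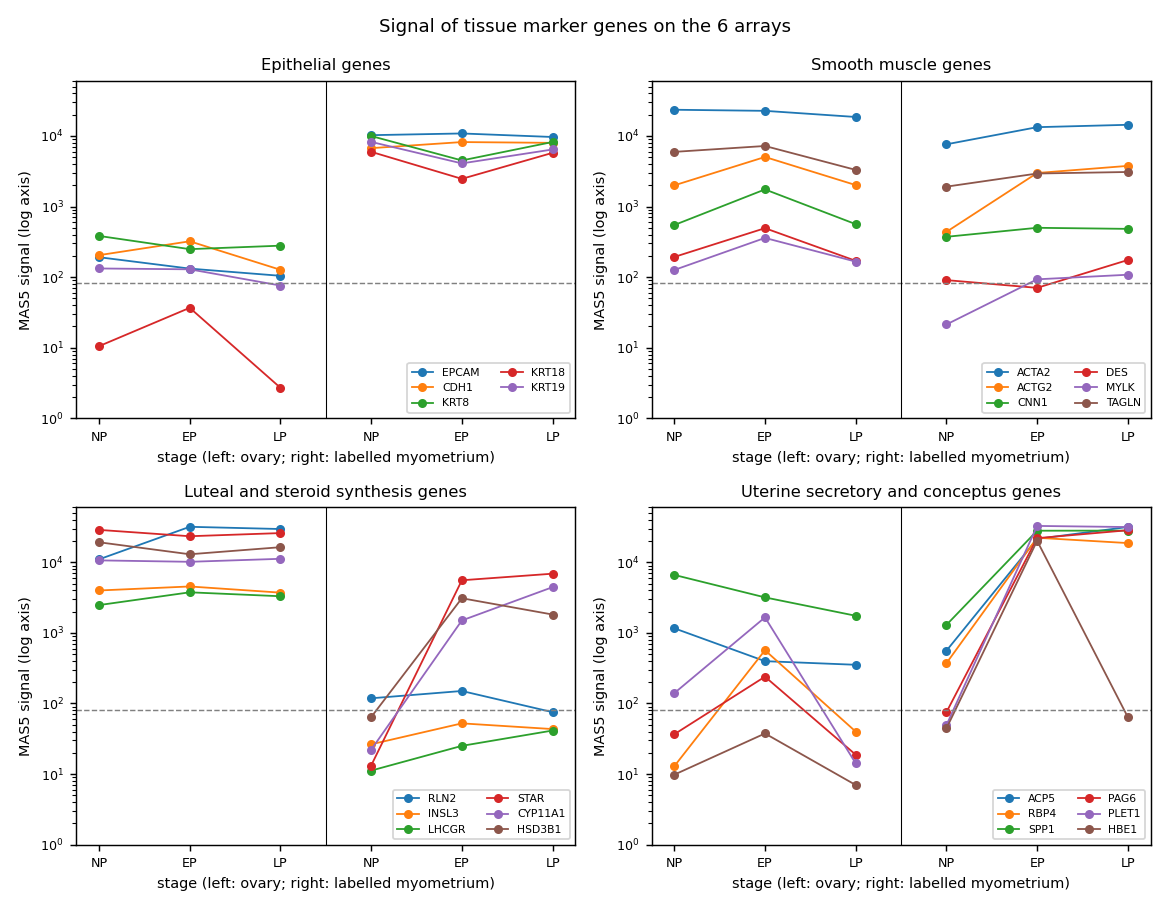
Signals (log axis) of marker genes on the 6 arrays, with ovary at the left and tissue labelled myometrium at the right of each panel, stages in the order non-pregnant (NP), early pregnant (EP) and late pregnant (LP), and the floor as a dashed line; each point is 1 array. EPCAM reads between 9667 and 10845 on the arrays labelled myometrium and between 104 and 191 in ovary, and PLET1 reads 49.1 on the non-pregnant and 32821 on the early pregnant array labelled myometrium.

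Lists of progesterone synthesis, follicle and luteal hormone genes lay toward ovary. The oestrogen and androgen synthesis list did not pass (camera adjusted p = 0.695, 1 of 7 genes higher in ovary). Its median was -0.89 in the early pregnant pair of arrays. Among the added placental markers, however, CYP19A3 read 8691, 5060 and 7198 on the ovary arrays in order of stage. On the arrays labelled myometrium CYP19A3 read at most 131. Of 15 progesterone synthesis genes, 5 were higher in ovary, 1, the mitochondrial protein TSPO, was higher on the arrays labelled myometrium and 9 did not pass. Adjusted over the list alone, 11 were higher in ovary and 2 on the other arrays. The median was 2.32 (camera adjusted p = 3.61e-05, adjusted p = 0.650 with an estimated correlation). NR5A2, a nuclear receptor of steroid-producing cells, differed by 5.82, and SCARB1, the receptor for high-density lipoprotein, by 3.77. STAR, which moves cholesterol into mitochondria, and CYP11A1, which makes pregnenolone from it, did not pass (adjusted p = 0.139 and 0.112). Both read far higher on the pregnant than on the non-pregnant array labelled myometrium. Of 13 follicle and granulosa genes, 7 were higher in ovary (11 adjusted over the list alone), including the inhibin subunit INHA (5.55), SERPINE2 (4.69) and follistatin FST (4.01). NR5A2, INHA and SERPINE2 each lay under the floor on 1 array labelled myometrium. That list had a median of 1.82 (camera adjusted p = 5.53e-07, adjusted p = 0.542 with an estimated correlation). In the luteal hormone list, RLN2, INSL3, LHCGR and the prostaglandin receptor PTGFR were higher in ovary, 4 of 8 genes and also 4 adjusted over the list alone, and the median was 1.65 (camera adjusted p = 0.0234, adjusted p = 0.542 with an estimated correlation). The oocyte list (median 1.28, camera adjusted p = 0.0174, 1 of 5 genes, ZP4) and the contraction list (0.69, adjusted p = 0.0165, 1 of 14 genes, PTGFR) also lay toward ovary, each with adjusted p = 0.542 with an estimated correlation. Adjusted over the list alone, 3 oocyte and 6 contraction genes were higher in ovary, and 1 contraction gene was higher on the arrays labelled myometrium. Of 19 complement genes, 4 were higher in ovary, namely C7, C4A, C3 and PROS1, or 8 with 3 in the other direction adjusted over the list alone. Their median was 0.47 (camera adjusted p = 0.0408, adjusted p = 0.784 with an estimated correlation). The ribosomal protein list (0.23, camera adjusted p = 3.61e-05, adjusted p = 0.542 with an estimated correlation) had 0 of 31 members past the threshold, over all genes or adjusted over the list alone, and its call ended under quantile normalization (adjusted p = 0.159). The contraction list's call ended when a gene's probe sets were averaged (adjusted p = 0.0741). The other 22 lists did not pass. In the prostaglandin list, the median was negative and the tested direction was ovary. In the adipocyte list, the median was positive and the mean and tested direction were toward myometrium. In the fibrillar matrix list, the median was positive and the mean just below 0, and in the inflammatory list the median was negative and the mean positive.

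Among the largest single differences, SELENBP1, a selenium-binding protein, was 68.0-fold higher in ovary (log2 difference 6.09 ± 0.45, SE, adjusted p = 0.00626). The tight junction gene CLDN11 was 27.0-fold higher, DAPL1 25.4-fold and FST 16.1-fold. LRP8, C7, the glutathione transferases GSTA1 and GSTA4, MCRIP2, PTGFR and DKK3 were between 9.50-fold and 13.1-fold higher there. INSL3 was at least 49.9-fold and the luteinizing hormone receptor LHCGR at least 38.4-fold higher in ovary. The melanocortin receptor accessory protein MRAP was at least 21.7-fold higher, ACSL6 at least 10.3-fold, CSDC2 at least 7.57-fold and the transcription factor GATA4 at least 6.75-fold. On the arrays labelled myometrium, EPCAM was 74.2-fold higher, the secreted protease inhibitor SLPI 52.8-fold, CDH1 37.5-fold and KRT8 24.0-fold. OCLN, SPINT2, DSP, CKB, PSPH, MYO5B, S100A14 and the matrix proteoglycan LUM were between 7.97-fold and 23.5-fold higher there. The calcium-binding protein S100G was at least 76.6-fold higher, KRT18 at least 53.8-fold and the claudins CLDN7 and CLDN4 at least 37.5-fold and 35.8-fold. SLC15A2 and SMIM22 were at least 33.6-fold and 27.7-fold higher.

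By limma, 451 probe sets were higher in ovary and 354 in tissue labelled myometrium among 15882 tested, which named 167 and 143 genes. The counts fell whichever stage was left out. Without the early pregnant arrays 0 passed in either direction (1790 at an unadjusted p under 0.05). Leaving out the non-pregnant arrays gave 138 higher in ovary and 260 in tissue labelled myometrium, and leaving out the late pregnant arrays 109 and 118. These fits have fewer residual degrees of freedom than the full fit, so they cannot show that the calls rest on a particular stage. Without the filter on low signals 0 passed in either direction (2782 at an unadjusted p under 0.05), and the variance prior had 0.82 degrees of freedom in place of 3.75.

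No stage change shared by both tissues passed the test. Interferon-induced genes showed the same direction in both tissues between early and late pregnancy without passing. MX1, an antiviral protein, read 2156 in the early and 453 in the late pregnant ovary, and 1951 and 299.9 on the corresponding arrays labelled myometrium. By limma, 0 of 15882 probe sets differed in each of the contrasts. At an unadjusted p under 0.05, 686 did between early pregnant and non-pregnant, 964 between late pregnant and non-pregnant and 261 between late and early pregnant.

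The design grouped pigs by stage to find genes that differ between stages, and the following comparisons have no replicate check and no p-value. Lists are named where their median lay outside the middle 95% of random lists. In the early pregnant ovary, luteal hormone genes were higher than in the non-pregnant ovary, while genes induced by interferon and genes of macrophages were lower. Relaxin, RLN2, read 11029 in the non-pregnant and 31899.6 in the early pregnant ovary. PCSK1, an enzyme that cuts prohormones, was at least 59.3-fold higher, from 65.5 to 4848. Of 20 interferon response genes, 8 were 2-fold or more lower and 0 higher, with a median log2 ratio of -0.89. MX1 was 4.33-fold and IFIT3 4.11-fold lower. The GAPDH ratio was also lower on the early pregnant ovary array (2.33 and 1.99), as were the poly-A controls (1343 and 988) and the 28S ribosomal RNA probe set (7783 and 5071). The 18S ribosomal RNA probe set went the other way (3647 and 5393).

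Of 7 luteal hormone genes, 3 were 2-fold or more higher in the early pregnant ovary (median 0.76), with angiotensinogen AGT at 1.73, RLN2 at 1.53 and PTGFR at 1.09 on the log2 scale. Smooth muscle genes were higher as a list (median 0.32), with 5 of 21 at 2-fold or more, among them SYNM (2.28), the calponin CNN1 (1.68) and the kinase MYLK (1.51). The fibrillar matrix list (median 0.41, led by LUM at 1.69 and LOX at 1.33), the contraction list (0.45) and the complement list (0.21) also lay higher. So did the immediate early list (0.44), in which FOS had a ratio of 1.76. Of 11 macrophage genes, 3 were 2-fold or more lower and 0 higher (median -0.67), with SPI1 at -1.41, CD86 at -1.16 and CD163 at -1.09. The cell cycle list had a median of -0.46, with 1 of 20 genes, CENPF, 2-fold or more lower, and the oxidative phosphorylation list one of -0.29. The uterine epithelium list lay lower (-0.48), with ACP5 at -1.55 and SPP1 at -1.06, but its member RBP4, a retinol carrier, went the other way. In all, 7 of its 10 measured genes lay below 0 and 3 above. Its epithelial members read low in ovary: EPCAM 191.3 and 131.9, KRT8 383.0 and 248.8, and CDH1, which rose, 204.5 and 321.6.

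Other genes with large ratios included PLET1, 11.9-fold higher in the early pregnant ovary (140.0 and 1661). PLET1 read 32821 and RBP4 22309 on the early pregnant array labelled myometrium. ALDH1A1, which makes retinoic acid, was 8.46-fold higher, PDLIM3 7.83-fold, lipoprotein lipase LPL 7.42-fold, ASPN 6.01-fold, C7 4.99-fold and haptoglobin HP 4.66-fold. KIAA1324 was at least 10.8-fold and RBP4 at least 6.96-fold higher, although another RBP4 probe set had a log2 ratio of -0.69. FABP3, a fatty acid carrier, was 4.91-fold lower, ATP5I 4.11-fold, GGT1 4.04-fold, FABP4 3.74-fold and KIF5B 3.57-fold. MRO was at least 16.4-fold lower, BSP1 at least 7.12-fold and PML at least 4.58-fold. In all, 373 of 15237 measured probe sets were 2-fold or more higher and 327 lower, and 9 of 31 lists lay higher and 6 lower. Of 42 genes with a further probe set whose brightest passed 2-fold, the next probe set went the same way in 35 and passed 2-fold in 19. The matrix protease list (-0.42) lost its place outside the random range under quantile normalization, the adipocyte list (0.39) and the inflammatory list (0.21) with the higher floor, and the nerve list (0.39) with that floor or averaged probe sets.

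**Figure D2:**
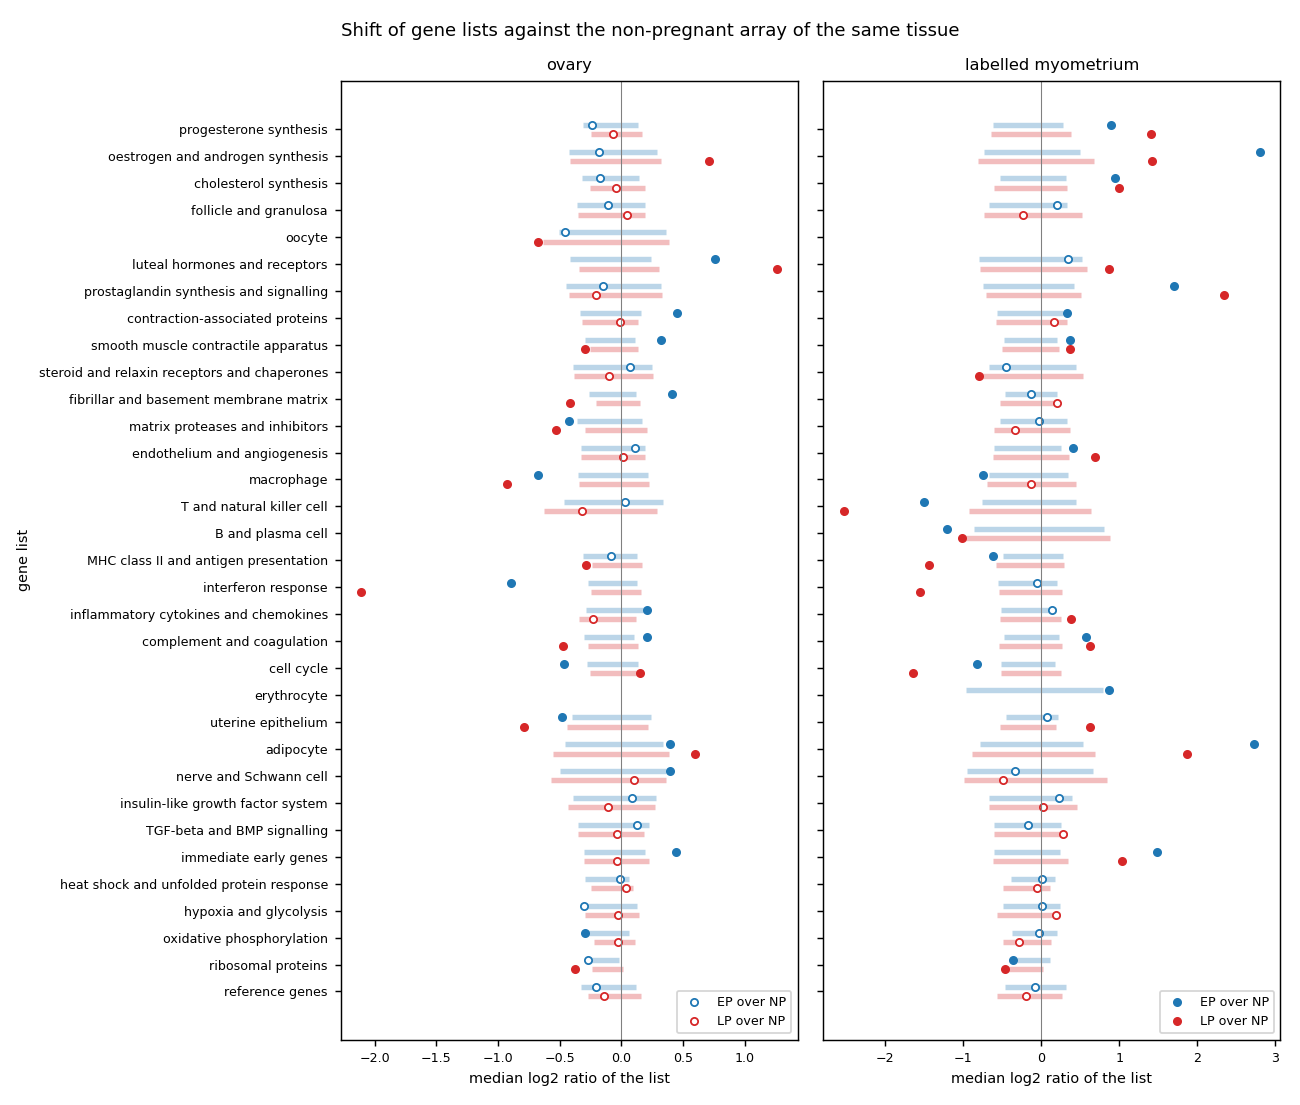
Median log2 ratio (x axis) of each gene list (y axis) in the early (EP, blue) and late (LP, red) pregnant array over the non-pregnant (NP) array of the same tissue, with bars for the middle 95% of random lists and filled points for medians outside it. The interferon response list lies at -0.89 and -2.11 in ovary.

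In the late pregnant ovary, genes induced by interferon were far lower than in the non-pregnant ovary, and macrophage genes were lower with them. Of 20 interferon response genes, 16 were 2-fold or more lower and 0 higher (median -2.11). RSAD2, an antiviral enzyme, was at least 29.5-fold lower, from 2412 to 75.1. MX1 was 20.6-fold lower, the ubiquitin-like ISG15 13.7-fold and IFIT3 12.7-fold. Haptoglobin, HP, read 672 and 14136, a log2 ratio of 4.40, and PCSK1 was at least 96.9-fold higher. The GAPDH ratio (2.33 and 1.51), the poly-A controls (1343 and 760.2) and 28S RNA (7783 and 3986) were lower on the late pregnant ovary array as well, whereas the actin ratio was 3.38 and 3.22 and had been 2.56 in early pregnancy.

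The macrophage list had a median of -0.92 in this comparison, with 5 of 11 genes 2-fold or more lower, among them CD86 (-1.24), FCER1G (-1.22) and TYROBP (-1.17). Luteal hormone genes were higher (median 1.26, 4 of 7 genes, and 0.55, 3 of 7, with averaged probe sets), with AGT at 2.51, RLN2 at 1.43 and VEGFA at 1.29, while 2 lay below 0. The oestrogen and androgen synthesis list had a median of 0.71, with HSD17B4 at 1.78 and HSD17B2, which inactivates oestradiol, at 2.29 or more. Fibrillar matrix (-0.41), matrix protease (-0.53) and smooth muscle (-0.30) lists lay lower, with the proteoglycan BGN at -1.60, the protease inhibitor TIMP1 at -1.85 and TAGLN at -0.85. Of 18 complement genes, 4 were 2-fold or more lower (median -0.47), including C2, C1S and C1R. The uterine epithelium list lay at -0.79, with SPP1 at -1.92 and ACP5 at -1.72, and 2 of its 10 measured genes lay above 0. EPCAM and CDH1 read 104.3 and 126.9 on the late pregnant ovary array, close to the floor.

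TDH was 15.6-fold higher in the late pregnant than in the non-pregnant ovary, the peptidase DPP4 13.4-fold, LPL 11.5-fold, the actin-severing protein SCIN 8.95-fold, ALDH1A1 7.33-fold, PLBD1 6.96-fold and PDLIM3 6.91-fold. KIAA1324 was at least 17.5-fold and kininogen KNG1 at least 10.1-fold higher. Besides the interferon genes XAF1 (11.4-fold), IFIT1 (11.3-fold) and USP18 (5.99-fold), PLAC8 was 8.46-fold and AMBN 5.20-fold lower. MRO was at least 16.4-fold and BSP1 at least 7.12-fold lower. In all, 439 of 15039 probe sets were 2-fold or more higher and 549 lower, and 4 lists of 31 lay higher and 10 lower. Quantile normalization turned the balance of the probe sets to 502 higher and 450.0 lower. The next probe set passed 2-fold in the same direction for 27 of 56 genes. The ribosomal list (-0.38) lay at the 58.9th percentile under quantile normalization, the antigen presentation (-0.29) and adipocyte (0.59) lists lost their place with averaged probe sets, and the oocyte (-0.68), complement and cell cycle (0.15) lists with the higher floor.

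Between early and late pregnancy, the ovary showed lower smooth muscle, matrix and interferon genes and higher cell cycle genes. Of 21 smooth muscle genes, 7 were 2-fold or more lower in late pregnancy and 0 higher (median -0.61), with SYNM at -1.82, CNN1 at -1.63 and desmin DES at -1.54. Of 20 matrix genes, 6 were lower (-0.62), led by LOX (-1.78), which crosslinks collagen, and COL3A1 (-1.57). The cell cycle list had a median of 0.60, with CDC20, an activator of mitotic exit, at 1.11. HSD17B1, which makes oestradiol, read 4560 in early and 12061 in late pregnancy, and 3 of 6 oestrogen and androgen synthesis genes were 2-fold or more higher (median 1.02). Between these arrays the GAPDH ratio was 1.99 and 1.51, the actin ratio 2.56 and 3.22 and the poly-A controls 988 and 760. The 28S probe set read 5071 and 3986, and the 18S probe set 5393 and 1806.

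Of 19 interferon genes, 11 were 2-fold or more lower in late than in early pregnancy (median -1.44), with RSAD2 at least 9.29-fold and MX1 4.76-fold lower. The complement (-0.47) and immediate early (-0.59) lists also lay lower, with FOS at -1.90 and JUN at -1.71, as did the macrophage (-0.36), matrix protease (-0.32) and antigen presentation (-0.17) lists. Cholesterol synthesis (0.37) and oxidative phosphorylation (0.32) lay higher. TDH was 6.88-fold higher, the glutathione-cleaving enzyme GGT1 6.59-fold, the surfactant protein SFTPC 5.10-fold, DPP4 4.76-fold, SCIN 4.56-fold, HP 4.52-fold, KNG1 4.40-fold and ADGRG1 4.22-fold. The opioid receptor OPRM1, AFM and transferrin TF were at least 6.30-fold, 5.11-fold and 4.55-fold higher. ASPN was 4.32-fold lower, XAF1 4.31-fold, DPPA5 3.94-fold and FIBIN 3.68-fold, and ISG15 read 1872 and 467. PLET1 was at least 20.3-fold and RBP4 at least 6.96-fold lower, although another RBP4 probe set had a log2 ratio of 0.29. In all, 221 of 14775 probe sets were 2-fold or more higher and 400 lower, with 4 lists of 31 higher and 12 lower, and the next probe set passed 2-fold for 13 of 28 genes. The contraction (-0.25), inflammatory (-0.34), TGF-beta (-0.32) and ribosomal (-0.12) lists lost their place under at least 1 alternative.

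**Figure D3:**
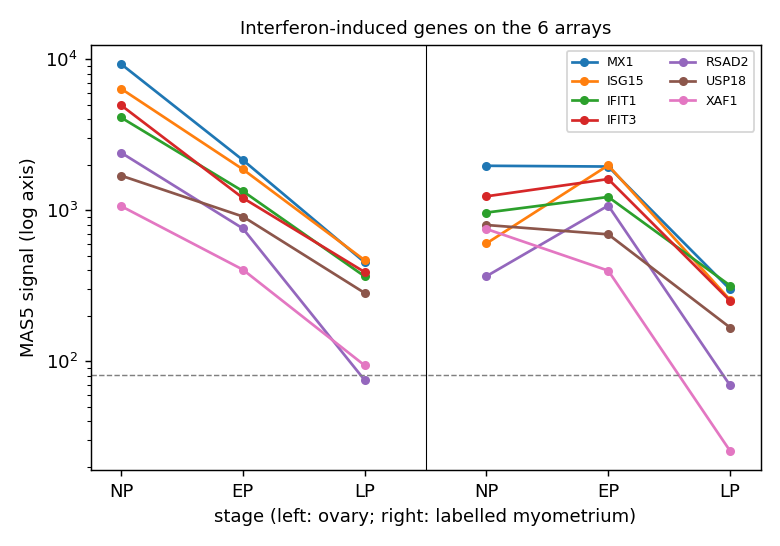
Signals (log axis) of 7 interferon-induced genes on the 6 arrays, ovary at the left and tissue labelled myometrium at the right, with stages ordered non-pregnant (NP), early pregnant (EP) and late pregnant (LP) and the floor dashed; each point is 1 array. MX1 reads 9325, 2156 and 453 across the ovary stages.

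On the early pregnant array labelled myometrium, UPTI, ACP5, PAG6 and HBE1 were far higher than on the non-pregnant array, while lymphocyte and cell cycle genes were lower. UPTI, a uterine protease inhibitor, read 91.2 and 22272, a 244-fold difference by its brightest probe set, while its other probe set had a log2 ratio of 0.84 or more, the non-pregnant array being at the floor. ACP5, uteroferrin, which carries iron, was 38.4-fold higher. The uterine epithelium list as a whole lay inside the random range (median 0.08), with 6 of 19 genes 2-fold or more higher and 4 lower. The placental aspartic protease family member PAG6 read 75.2 and 22022, and the embryonic globin HBE1 44.3 and 20201. Steroid enzymes were higher too: STAR read 13.2 and 5573, and CYP11A1 22.1 and 1502. PAG6 was chosen after its values were seen. Between these arrays the actin ratio was 3.49 and 2.64, the GAPDH ratio 1.52 and 1.70, the poly-A controls 829.9 and 676 and 28S RNA 4519 and 7575.

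Of 8 oestrogen and androgen synthesis genes, 7 were 2-fold or more higher (median 2.80, or 2.08 with averaged probe sets). Among them, HSD17B2, which inactivates oestradiol, was at 6.89 or more and the oestrogen sulfotransferase SULT1E1 at 5.29 or more on the log2 scale. The median of this list is thus not a measure of oestrogen synthesis alone. The progesterone (median 0.89, 5 of 13 genes) and cholesterol (0.94, 6 of 12) synthesis lists also lay higher. Among luteal markers, RLN2 read 118.5 and 150.4 and LHCGR 11.2 and 25.1 on the non-pregnant and early pregnant arrays, while PTGFR read 336 and 1319.9 and SCARB1 684 and 884. In the prostaglandin list (1.71, 5 of 8, and 0.85, 3 of 8, with averaged probe sets), the synthase PTGS2 was at 3.87 or more and CBR1 at 5.92 or more, whereas PTGDS was at -3.17. Of 14 immediate early genes, 8 were higher (1.49), led by ATF3 (3.11) and IER3 (2.58). The smooth muscle list had a median of 0.37, with 2 of 21 genes higher, ACTG2 (2.77) and MYL9 (1.58). The contraction list (0.33), which PTGS2 led, lost its place with the higher floor.

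Of 8 T and natural killer cell genes, 6 were 2-fold or more lower (median -1.50), with CD3E at -2.19 and CD8A at -1.77. Among B and plasma cell genes, 3 of 4 were lower (-1.21), led by JCHAIN (-2.37), the joining chain of secreted antibodies. The cell cycle list had a median of -0.82, with 7 of 22 genes lower, including MCM5 (-1.50) and CCNB1 (-1.24). The macrophage list lay at -0.75 (mean -0.20), but at 2-fold 2 of its 11 genes were higher, with AIF1 at 2.43, and 1 lower. The antigen presentation (-0.61) and ribosomal (-0.36) lists lay lower and lost their place with averaged probe sets, and the ribosomal list under quantile normalization as well. The complement list lay higher (0.57), with tissue factor F3 at 2.58.

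The sulfotransferase SULT2A1 was 239-fold higher on the early pregnant array, PLBD1 180-fold, DPP4 41.7-fold and the Wnt inhibitor DKK1 32.4-fold, and RBP4 had a log2 ratio of 5.91. PLET1, UABP-2 and DPPA5 were at least 402-fold, 329-fold and 303-fold higher, although the other PLET1 probe set had a log2 ratio of 2.66 or more. FNTA was 45.8-fold higher by its brightest probe set, while its other probe set had a log2 ratio of -0.58, and 1 of 3 further PLBD1 probe sets was also opposite (-0.38). The chemokine CCL28 was 34.0-fold lower, PHGDH, an enzyme of serine synthesis, 31.3-fold, UPK3A 25.2-fold, PDZK1 15.9-fold, S100G 13.8-fold, alkaline phosphatase ALPL 13.4-fold, UPK1B 12.6-fold and ATP6V0D2 10.6-fold. The phosphate transporter SLC34A2, the calcitonin receptor CALCR and TMC5 were at least 54.8-fold, 15.1-fold and 10.9-fold lower. In all, 1388 of 15836 probe sets were 2-fold or more higher and 1631 lower. The median over all measured probe sets was -0.17, and centring the arrays on their medians, which moved it to -0.03, turned the counts to 1738 higher and 1176 lower. Lists lay higher in 11 of 32 cases and lower in 6, and the next probe set passed 2-fold in the same direction for 100 of 190 genes.

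On the late pregnant array labelled myometrium, PAG6, ACP5 and PLAC1 were high against the non-pregnant array, and steroid receptor, lymphocyte and cell cycle genes were low. PAG6 was at least 349-fold higher, ACP5 56.8-fold and PLAC1, a gene of trophoblast, 68.4-fold, from 118 to 8035. The progesterone receptor PGR was 15.1-fold lower, from 1498 to 99.4, and the oestrogen receptor ESR1 read 902 and 67.8. JCHAIN was 65.7-fold lower. The actin ratio was 3.49 and 2.76, the GAPDH ratio 1.52 and 1.53, the poly-A controls 829.9 and 1097 and 28S RNA 4519 and 4359.8.

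The progesterone synthesis list had a median of 1.40, or 0.82 with averaged probe sets, with 8 of 13 genes 2-fold or more higher, among them STAR (13.2 and 6907), CYP11A1 (log2 ratio 5.77 or more) and HSD11B2 (4.01), which inactivates cortisol. Of 9 prostaglandin genes, 5 were higher (2.35, or 1.49 with averaged probe sets), including CBR1 (7.29 or more), PTGS2 (4.51 or more) and PTGFR (3.35). The uterine epithelium list had a median of 0.63, with 7 of 19 higher, led by UABP-2 (8.44 or more), ACP5 (5.83) and RBP4 (5.66). Oestrogen and androgen synthesis (1.42), cholesterol synthesis (0.99), luteal hormone (0.87), complement (0.63), smooth muscle (0.37) and immediate early (1.03) lists lay higher. In the luteal hormone list, 3 of 7 genes were 2-fold or more higher, including PTGFR, and 1, OXT, was lower (-2.60 or below). RLN2 read 118.5 and 75.4, and INSL3 and LHCGR lay under the floor on both arrays. Of 22 cell cycle genes, 18 were 2-fold or more lower and 0 higher (median -1.65), with CCNB1 at -3.43 and TOP2A at -3.04. The T and natural killer cell (-2.52, 7 of 8 genes) list also lay lower, with the chemokine CCL5 at -2.98, as did the B and plasma cell list (-1.01). Of 20 interferon genes, 15 were lower (-1.56), including OAS1 (-3.13) and IFIT2 (-2.89). Of 15 antigen presentation genes, 10 were lower (-1.43), with PSMB8 at -2.30. The steroid receptor list had a median of -0.80, with 4 of 9 genes lower, while the glucocorticoid receptor NR3C1 was at 1.85.

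SULT2A1 was 194-fold higher in late pregnancy than on the non-pregnant array, the bactericidal protein BPI 152-fold, PLBD1 136-fold, UPTI 57.5-fold, the fructose transporter SLC2A5 54.0-fold and RBP4 50.4-fold. The other UPTI probe set had a log2 ratio of 0.10 or more, and 1 of 3 further PLBD1 probe sets was opposite (-0.34). PLET1 and HP were at least 387-fold and 377-fold higher. SLC28A3 was 26.4-fold lower, VNN2 13.3-fold, the metallothionein MT3 12.8-fold, PHGDH 12.7-fold, CLDN11 12.2-fold and ALDH1A1 11.7-fold. CCL28, SLC34A2 and ALPL were at least 61.9-fold, 54.8-fold and 37.0-fold lower. In all, 1744 of 16013 probe sets were 2-fold or more higher and 2020 lower, with a median of -0.14 over all. Centring the arrays on their medians moved it to -0.04 and the counts to 1990 higher and 1690 lower. Lists lay higher in 12 of 31 cases and lower in 7, and the next probe set passed 2-fold for 120 of 247 genes. The ribosomal list (-0.46) lost its place under quantile normalization and the inflammatory list (0.38) with averaged probe sets.

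Between early and late pregnancy, the arrays labelled myometrium differed in interferon and cell cycle genes, which were lower in late pregnancy. Among single genes, HBE1 and DPPA5 were lower and HP and PEG10 higher. HBE1 was at least 247-fold lower, DPPA5, a gene of pluripotent cells, 92.8-fold lower, and interferon gamma, IFNG, read 1720 and 64.8, the latter under the floor. HP was 34.5-fold higher, from 893 to 30784, and PEG10, an imprinted gene of placenta, 19.1-fold higher. Of 20 interferon response genes, 12 were 2-fold or more lower (median -1.95), with RSAD2 at -3.72 or below and ISG15 at -2.96. The poly-A controls read 676 and 1097 and 28S RNA 7575 and 4359.8, while the actin ratio was 2.64 and 2.76.

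The cell cycle list had a median of -1.09, with 11 of 21 genes lower, including CCNB1 (-2.19) and CENPF (-1.98). Of 8 oestrogen and androgen synthesis genes, 6 were lower (-1.66), with HSD17B2 at -2.61 and CYP19A1, aromatase, at -2.87 or below. The antigen presentation (-0.75) and immediate early (-0.37) lists lay lower too. Of 9 prostaglandin genes, 4 were higher (0.79), including PTGDS at 1.68 and PTGFR at 1.38. AOAH was 20.9-fold higher, FAXDC2 and UPK1B 13.3-fold, PLAC1 12.7-fold and C1QTNF2 12.5-fold, and RBP7 had a log2 ratio of 3.81. ETNPPL and PHEROC were at least 98.6-fold and 11.2-fold higher, and ADAMDEC1 read 23.4 and 1303.5. SERPINB7 was 19.3-fold lower, STEAP1 19.2-fold, JCHAIN 12.7-fold, DKK1 11.3-fold, the chemokine CXCL14 11.2-fold, ALDH1A1 11.1-fold and CTH 10.8-fold. In all, 912 of 15537 probe sets were 2-fold or more higher and 873 lower, which centring turned to 870 and 974. Lists lay higher in 5 of 30 cases and lower in 6, and the next probe set passed 2-fold for 50 of 107 genes. The progesterone (0.30), fibrillar matrix (0.20), uterine epithelium (0.16) and T and natural killer cell (-0.55) lists lost their place under at least 1 alternative.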

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

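Several genes and lists had ratios of opposite sign in the ovary and in tissue labelled myometrium between the same stages. Each tissue had 1 array per stage, so none of these differences was tested. The values below are log2 ratios in ovary, then on the arrays labelled myometrium, then the first minus the second.

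Between non-pregnant and early pregnant arrays, the matrix protein ASPN had ratios of 2.59 and -1.70 (difference 4.28), FABP3 of -2.30 and 2.07 (-4.36) and GGT1 of -2.02 and 1.29 (-3.31). Uteroferrin, ACP5, had ratios of -1.55 and 5.26 (-6.81), and alkaline phosphatase, ALPL, 1.17 and -3.74 (4.91).

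Between non-pregnant and late pregnant arrays, ALDH1A1 had ratios of 2.87 and -3.55 (6.42), BPI of -1.16 and 7.25 (-8.41), ACP5 of -1.72 and 5.83 (-7.55) and ALPL of 2.12 and at most -5.21 (7.33 or more). Between early and late pregnant arrays, DPP4 had ratios of 2.25 and -3.28 (5.53), FAXDC2 of -1.12 and 3.73 (-4.86) and PHEROC of -1.35 or below and 3.49 or above (-4.83 or below).

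Among lists, the late pregnant against non-pregnant medians were -0.30 and 0.37 for smooth muscle (-0.67), -0.47 and 0.63 for complement and coagulation (-1.10), 0.15 and -1.65 for cell cycle (1.80) and -0.79 and 0.63 for uterine epithelium (-1.42). The late against early pregnant medians were 1.02 and -1.66 for oestrogen and androgen synthesis (2.69), -0.62 and 0.20 for fibrillar matrix (-0.82) and 0.60 and -1.09 for cell cycle (1.70). With the higher floor, the late pregnant against non-pregnant complement and cell cycle medians in ovary lost their place outside the random range. The fibrillar matrix median on the arrays labelled myometrium lost its place under an alternative too. Epithelial members of the uterine epithelium list read low in ovary.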

How the results depend on the processing

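Counts at 2-fold depended mainly on the floor, and the tests between tissues on the filter and the arrays. With the floor at the 60th percentile, 298 probe sets were higher in ovary and 179 in tissue labelled myometrium. Without the low-signal filter 0 passed in either direction, with 23999 probe sets tested in place of 15882. That setting admits probe sets at the floor on most or all arrays. The variance prior then had 0.82 degrees of freedom in place of 3.75, so the number of tests was not the only change. The shared stage counts became 4 for early pregnant against non-pregnant and 3 for late pregnant against non-pregnant. Without the stage block, 715 were higher in ovary. Leaving out a stage in turn gave 0 to 138 higher in ovary and 0 to 260 higher in tissue labelled myometrium, with 1 residual degree of freedom. With an estimated correlation 0 of the 9 lists called between tissues passed. That setting rests on 2 residual degrees of freedom. It gave the uterine epithelium list (median -3.73) and the ribosomal protein list (0.23) the same adjusted p of 0.542. It could hardly call any list, so it cannot decide whether a call holds. The preset correlation of 0.01 takes the members of a list as nearly independent, so its small p-values cannot decide this either. With the late pregnant arrays alone, an alternative chosen after seeing the data, the smooth muscle median turned to -0.038; the cause was not tested.

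With the floor at the 25th percentile, ovary counts at 2-fold became 687 higher and 829 lower (early pregnant over non-pregnant), 1324 lower (late pregnant over non-pregnant) and 392 higher and 893 lower (late over early pregnant). In tissue labelled myometrium they became 2452 lower (early pregnant over non-pregnant) and 1514 higher and 1423 lower (late over early pregnant). With the floor at the 60th percentile, the ovary counts in that order were 185 and 122, 269 and 198, and 104 and 181. In tissue labelled myometrium they were 913 and 893, then 1163 lower, then 502 and 428. With the pseudocount, 504 and 848 probe sets were lower in the early and late pregnant ovary against the non-pregnant. A higher floor leaves fewer probe sets to count by construction. Of the measured probe sets, 8.76% were higher on the early pregnant array labelled myometrium, and 8.37% with the floor at the 60th percentile. In the early pregnant ovary, 2.15% and 1.19% were lower. Quantile normalization and median centring left all counts within 1.5 times, but quantile normalization turned which direction had more in the late pregnant ovary against the non-pregnant and in each comparison of tissue labelled myometrium.

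Of the 92 list medians called between stages, 84 kept their call under quantile normalization, 82 with averaged probe sets and 78 with the higher floor, where 10 lost it and the others had too few measured genes. With averaged probe sets, the log2 ratios of named genes with several probe sets moved by more than the spread between probe sets for 39 and stayed for 8 between stages. Between tissues 13 moved by more than the standard error and 4 stayed. No paired analysis was possible by animal because the labels give no animal numbers, and the fit between tissues has stage as its block.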

Other observations

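Vessel genes were higher on the pregnant than on the non-pregnant arrays labelled myometrium. Of 14 measured endothelial genes, 3 were 2-fold or more higher on the early pregnant than on the non-pregnant array (median log2 ratio 0.41), and 5 of 15 on the late pregnant array (0.69). VEGFA, a growth factor for vessels, read 818 on the non-pregnant, 3604 on the early pregnant and 3209.5 on the late pregnant array, and the endothelial claudin CLDN5 read 132, 348 and 444. Both list medians lay outside the middle 95% of random lists. In ovary the endothelial list lay inside that range in each comparison, while VEGFA read 1172, 1979 and 2865.

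Genes of the adipocyte list were also higher on the pregnant arrays labelled myometrium. In the adipocyte list, 4 of 6 measured genes were 2-fold or more higher on the early pregnant array (median 2.72) and 4 of 6 on the late pregnant array (1.87). LPL read 102 on the non-pregnant, 1368 on the early pregnant and 365 on the late pregnant array, and the nuclear receptor PPARG 53.8, 869 and 559. In the erythrocyte list, adult globin HBB read 1440.1 on the non-pregnant, 501 on the early pregnant and 574 on the late pregnant array, whereas HBE1 was high on the early pregnant array alone. Between early and late pregnancy that list's median (0.70) and mean (-1.25) differed in sign.

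The weighing below rests on tests chosen after the results were seen. These include the split count, the marker lists of luteal and granulosa cells and of placenta, and the stages taken alone. For the 805 probe sets called between tissues, the 6 arrays make 10 splits into 3 and 3, of which 1, the real one, called as many, and the highest of the others called 0. So few splits cannot give a share under 0.05.

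The arrays labelled myometrium carried strong epithelial signal and no excess of smooth muscle genes. Exchanged labels are argued against by luteal and granulosa markers, since 9 of 10 were higher on every ovary array than on any array labelled myometrium. The exception, OXT, lay under the floor on each ovary array and read 495 on the non-pregnant array labelled myometrium. Unequal signal distributions are argued against as well, as the smooth muscle median was 0.71 after quantile normalization and 0.68 before. Both settings hold the arrays to a common level, so neither can show a change in the total amount of RNA. The values go with endometrium, the glandular lining of the uterus, in the uterine samples. The epithelium list was higher there at each stage, with the smallest of the 3 differences, -2.94, in the non-pregnant pair. In the pregnant pairs (-4.18 and -4.76), epithelium of conceptus tissue, weighed below, could not be told apart from endometrium. Smooth muscle of the ovary itself may also keep the difference in smooth muscle genes small. This, like a biological difference between tissues and stages, stays open as untested.

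The pregnant arrays labelled myometrium also carried placental transcripts and steroid enzymes. Of 13 measured genes of the placental list, 8 were 2-fold or more higher on the early pregnant than on the non-pregnant array, against 9.10% of all genes. Of the 9 members not named by the fixed rule, 5 were higher in this way. These values go with conceptus tissue in the samples. GATA3 read 59.2 and 3168, and HAND1 50.4 and 449, although DLX5 read 2063 on the non-pregnant array. Some members are not particular to placenta in these data. PTHLH and IGF2, both among the 8, read 1554 and 1464 in the early pregnant ovary. CYP19A3 read 5060 in that ovary and 131 on the early pregnant array labelled myometrium. Ovarian RNA as the source of the steroid enzymes is argued against: STAR and CYP11A1 reached 23.8% and 14.8% of their early pregnant ovary signals. The 90th percentile over 6 bright luteal and granulosa markers was 10.4% and their median 3.09%, with SCARB1 highest at 11.8%. On the late pregnant array the shares were 26.6% and 39.7%, against a median of 1.21% for the markers, of which PTGFR was highest at 20.5% and RLN2 lowest at 0.254%. Steroid enzyme expression in endometrium or placenta of pregnant sows stays open as untested.

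The early pregnant ovary array carried low signals of transcripts that were abundant on the early pregnant array labelled myometrium. Of 12 such transcripts under the floor on the other ovary arrays, PLET1 and RBP4 left out, 12 were highest on the early pregnant ovary array, against 37.4% of 1186 genes low on those arrays, and 8 lay above the floor there, against 6.58% of those genes. The same search found 4 of 14 for the late pregnant and 1 of 5 for the non-pregnant ovary. This is consistent with traces of uterine RNA, with a median excess of 0.870% of the uterine signal over those 8, among them UPTI (314) and PAG6 (239.8); the 4 others lay under the floor there. PLET1 reached 4.83% and RBP4 2.43%, above the 90th percentile of these shares at 1.33%. PLET1 lay at 85.1% of the brightest signal of the uterine array, where saturation could distort its share. SULT2A1 (26616) and UPTI (22272) were also bright there and had shares of 0.94% and 1.37%. Uterine RNA and expression in the ovary cannot be told apart for PLET1. RBP4 read 22309 there, close to UPTI. Its source stays undecided too, as its other probe set had a log2 ratio of -0.69 between the early pregnant and non-pregnant ovary.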
